A study of Methanosarcina barkeri str. Fusaro with 27 samples.

How the data were processed

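RNA of Methanosarcina barkeri Fusaro, 27 samples with 3 for each of 9 strains, was extracted with TRIzol, depleted of ribosomal RNA by subtractive hybridisation, made into stranded TruSeq libraries and sequenced on a HiSeq2000, per the labels. The submitters give CASAVA 1.8.2 for base calling. Aligner, counting tool and genome build are not given in the sources used here. The headers of the authors' deposited table say that trimmed single reads left unmapped by an earlier step were used, and they give lanes 3 to 7, where the labels describe a single lane.

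The authors' deposited table holds 3832 genes of the chromosome and a plasmid, of which 74 are rRNA or tRNA genes and 20 lie on the plasmid. Per the file headers it gives for each library counts of total gene reads and of unique gene reads, neither normalized, and RPKM, which the authors computed from total reads, gene length and a total per library. For each strain against the parent the authors also deposited a p-value, not adjusted, and a signed fold change from the EDGE test with tagwise dispersions. Gene starts and ends (other columns, per the file headers) are the same for all libraries. A separate location column of the deposited table equals those columns in 1063 of 3616 genes, being out of step from line 853 onward, so it was used for strand alone, found for 3597 genes. Of 358 columns 99 were read, and all 216 columns that belong to a library matched a sample.

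Total gene reads were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the strains as groups, which left 3075, libraries were scaled by TMM, and a single quasi-likelihood model with a mean per strain was fitted to all 27 libraries (glmQLFit with robust estimation, glmQLFTest). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.258 and the prior degrees of freedom 8.55. Counts of genes leave out the genes deleted in either strain of the comparison, the hpt candidate Mbar_A1633, and rRNA and tRNA genes. The standard error is the size of the log2 fold change divided by the square root of F. CPM use the scaled library sizes. There were 16 comparisons: 8 strains with the parent, 6 pairs in which 1 strain lacks all operons the other lacks and more, and 2 interactions.

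Gene lists, 33 in number, were defined by patterns on gene symbol and product text, so a list holds what the annotation names and can take in genes of other function. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Named genes are the 12 of highest and 12 of lowest fold change in comparisons with the parent and 5 of each elsewhere, among genes with an adjusted p under 0.05, a log2 change of at least 1 and a mean of at least 10 CPM in the higher strain, with all hydrogenase genes and the 4 members of smallest adjusted p in each list. The comparisons, tests, lists, naming rule and the other settings below, apart from the last pair, were fixed before the data were examined.

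Of gene reads 98.5 to 99.3% were unique. Genes took 70.9 to 82.0% of the mapped reads, and rRNA and tRNA genes at most 0.0222% of gene reads. Between libraries of a strain the spread exceeded counting error, with a chi-square per degree of freedom of 2.39 to 137. edgeR was tested on data simulated for frh against the parent, with 200 of 3023 genes changed. It called 50.0% of those changed 2-fold and 91.0% of those changed 4-fold, and 3.43% of calls were unchanged genes, rates for simulated data only. DESeq2 called 53.0% and 92.0%.

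The other settings were RLE size factors, no low-count filter, a filter at 10 CPM in 3 libraries, rRNA and tRNA kept, genes deleted in any strain removed, unique reads, a fit of only the strains compared, DESeq2 1.42.0, an estimated correlation for the lists, and each library left out in turn. Settings added after seeing the data were leaving out ech_frh replicate 1 and the library labelled ech_vht_frh replicate 3 together, and removing a trend with gene length, for genes and lists. Camera came from limma 3.58.1, and tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No paired analysis was possible because the labels pair no samples. GC content was not analysed here, since no genome sequence was at hand.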

Results

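Transcript levels were measured by strand-specific RNA sequencing in Methanosarcina barkeri Fusaro, a methane-producing archaeon, taken in mid-exponential growth on 125 mM methanol at high salt. The 27 libraries fall into 9 strains of 3 libraries each. They are the parental strain, 4 strains lacking a single hydrogenase operon (fre, vhx, ech or frh), and 4 strains lacking several: ech and frh (ech_frh), vht and frh (vht_frh), ech, vht and frh (ech_vht_frh), and every hydrogenase operon together with Mbar_A1842 and Mbar_A1843 (all_hydrogenase). Hydrogenases interconvert H2 with protons and electrons: Frh and Fre act with coenzyme F420, Vht and Vhx with the membrane carrier methanophenazine, and Ech with ferredoxin. By label the strains differ in more than these operons. The hpt locus carries attP in the parent, fre, vhx and ech strains and attB in the 5 strains without frh, and ech is replaced by pac-hpt in ech_frh and all_hydrogenase, by FRT in ech_vht_frh and by no marker in ech. At vht, FRT stands in vht_frh and ech_vht_frh and no marker in all_hydrogenase. Every comparison across these groups carries the marker or att difference too.

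Total gene reads per library ranged from 626694 to 2016250. By strain they were 1289316 to 1552440 in the parent, 1146157 to 1932589 in fre, 935481 to 1154916 in vhx, 834035 to 1138872 in ech, 999141 to 1894305 in frh, 1090855 to 1240289 in ech_frh, 1363769 to 1652434 in vht_frh, 626694 to 1045442 in ech_vht_frh and 1573114 to 2016250 in all_hydrogenase. A floor of 3 reads in a library corresponds to 1.49 to 4.79 CPM (counts scaled to library size), a limit that covers counting error only. Levels are given as mean CPM ± SD over n = 3 libraries, and changes as log2 fold change ± SE from edgeR's quasi-likelihood test. The labels do not say that the libraries of a strain came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The headers put each strain in 1 lane. The pairs within a lane were fre and the parent, vhx and ech, frh and ech_frh, and vht_frh and ech_vht_frh. In every other comparison of 2 strains lane and strain cannot be told apart.

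The deleted operons were read first, as a check of the labels. In the parent the frh operon (chromosome 547965 to 551556, 4 genes) summed to 14038 ± 655 CPM, vht (2306989 to 2311315, 4 genes) to 10498 ± 368, ech (166460 to 171543, 6 genes) to 2617 ± 145, fre (2898238 to 2901628, 4 genes) to 332 ± 24.7, and vhx (2300882 to 2304713, 3 genes) to 38.3 ± 4.73. Mbar_A1842 and Mbar_A1843 (2305065 to 2306533), which lie between vhx and vht, summed to 145 ± 7.22. Of the 51 pairs of a deleted operon and a library, 43 held at most 1% of the parental level. The other 8 were ech in ech_frh replicate 1 (4.01%) and in ech_vht_frh replicates 2 (6.16%) and 3 (2.74%), frh in ech_frh replicate 1 (5.87%) and ech_vht_frh replicate 3 (4.17%), vht in ech_vht_frh replicates 2 (5.07%) and 3 (50.1%), and fre in all_hydrogenase replicate 1 (1.08%). The library labelled ech_vht_frh replicate 3 therefore went against its label for vht, and every direction given below for ech_vht_frh includes it unless stated.

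**Figure D1:**
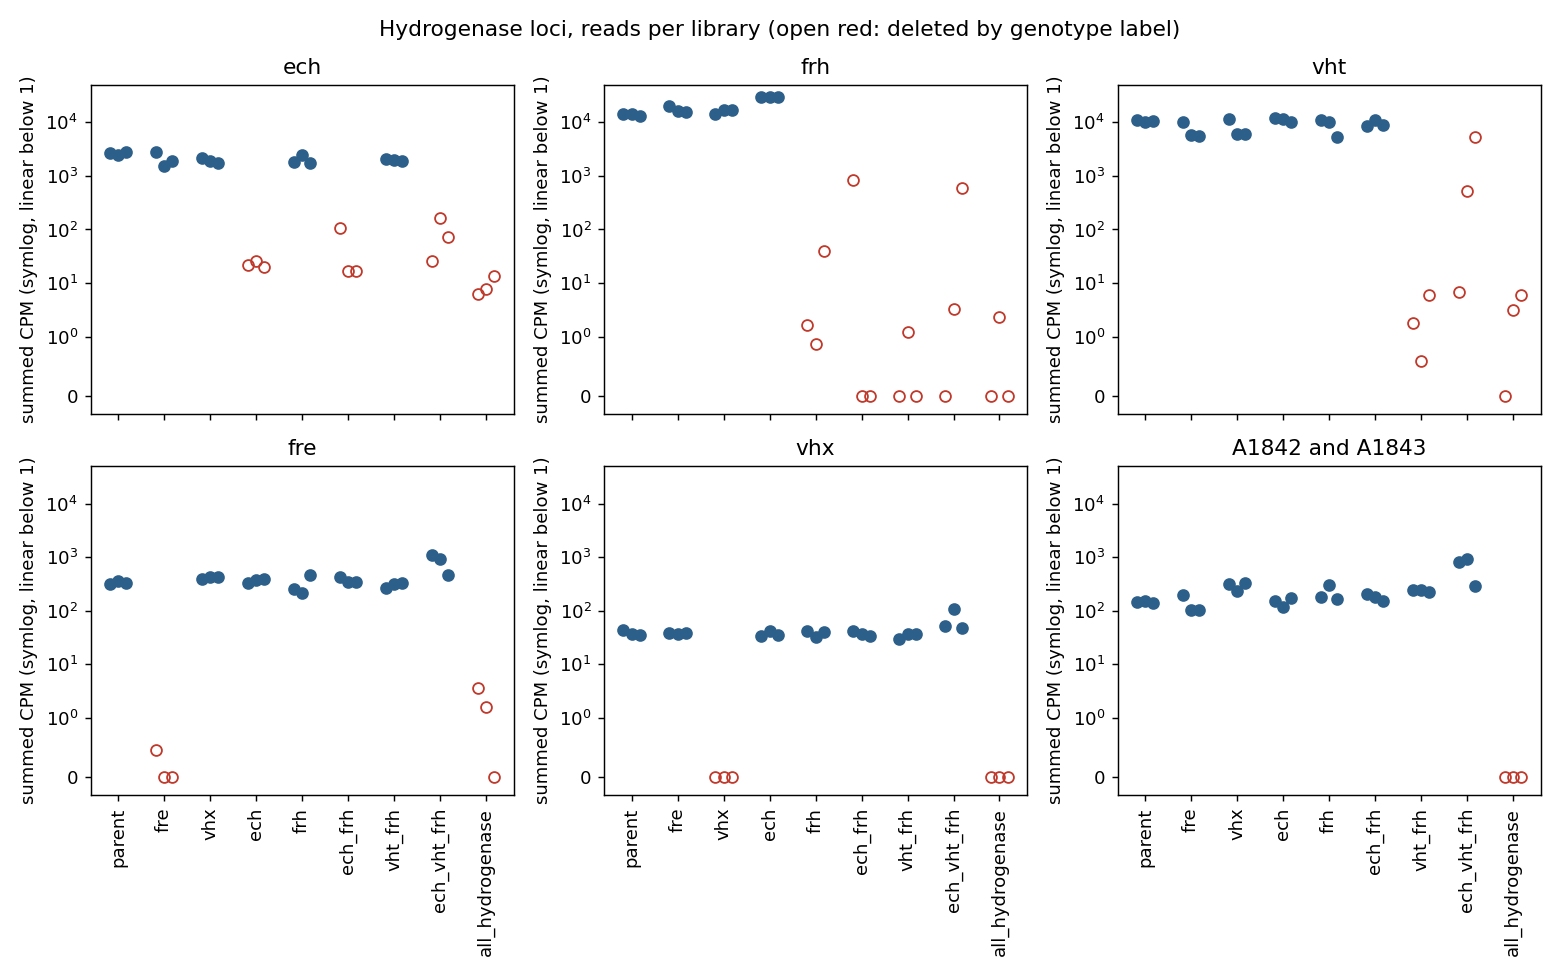
Summed CPM of each hydrogenase operon in each of the 27 libraries, on an axis that is logarithmic above 1 and linear below it; open red circles are libraries whose genotype label deletes the operon. Deleted operons lie far below the parent, except for vht in the library labelled ech_vht_frh replicate 3, which held 50.1% of the parental level.

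The frh operon read higher in the ech strain than in the parent, at 29688 ± 467 against 14038 ± 655 CPM. Its catalytic subunit gene frhA (Mbar_A0452) stood at 13172 ± 55.9 against 5681 ± 250.0 CPM, a log2 fold change of 1.21 ± 1.45 that was not called in the fit of 27 libraries (adjusted p = 0.686 by edgeR). In a fit of the ech and parental libraries alone all 4 genes were called, with adjusted p = 2.44e-06 for frhA, 4.71e-05 for frhB (Mbar_A0449), 1.97e-05 for frhG (Mbar_A0450) and 0.000555 for frhD (Mbar_A0451). The fit of 27 libraries gives frhA a single dispersion, estimated also from the 5 strains in which the gene is deleted.

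Loss of fre, the second F420-reducing hydrogenase operon, was accompanied by lower transcripts of the molybdenum formylmethanofuran dehydrogenase (fmd), which oxidises formylmethanofuran in the last step of methyl oxidation to carbon dioxide. The 4 genes Mbar_A1287 to Mbar_A1290 (1595272 to 1599598) changed by -1.09 ± 0.19, -1.14 ± 0.22, -1.28 ± 0.24 and -1.40 ± 0.25 log2 units (edgeR adjusted p = 0.00166, 0.00392, 0.00305 and 0.00166), and Mbar_A1289 fell from 1627 ± 147 to 669 ± 56.7 CPM. The largest increase was in Mbar_A3284, a hypothetical protein (6.58 ± 1.14, adjusted p = 0.00305, 72.0 ± 54.3 against 0.677 ± 0.663 CPM). Mbar_A2632 (hypothetical) rose by 5.42 ± 1.26 (adjusted p = 0.0254). The largest decreases were in the cytochrome c biogenesis gene ccdA (Mbar_A3428, -3.24 ± 0.70, adjusted p = 0.0119) and the hypothetical gene Mbar_A0478 (-3.08 ± 0.66, adjusted p = 0.0101).

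Methyl oxidation genes were lower, with 1 of 30 called higher and 6 lower (3 and 14 adjusted over the list alone). The methyl oxidation list had a camera adjusted p = 4.85e-05 (0.340, estimated correlation). Cofactor synthesis genes were lower, with 1 of 23 called higher and 6 lower (2 and 7 adjusted over the list alone). The cofactor list had a camera adjusted p = 0.0155 (0.340, estimated correlation). The cofactor list shares the fmd genes with the methyl oxidation list. Ribosomal protein genes were lower, with 0 of 61 called higher and 1 lower (0 and 0 adjusted over the list alone). The ribosomal list had a camera adjusted p = 8.66e-05 (0.570, estimated correlation). ATP synthase genes were lower as a list (median -0.74), with 0 of 18 called (0 adjusted over the list alone). The ATP synthase list had a camera adjusted p = 0.00150 (0.515, estimated correlation). Aminoacyl-tRNA synthetases were lower as a list (median -0.18), with 0 of 27 called (0 adjusted over the list alone). The synthetase list had a camera adjusted p = 0.0348 (0.570, estimated correlation). Phosphate uptake genes were lower as a list (median -1.04), with 0 of 5 called (0 adjusted over the list alone). The phosphate list had a camera adjusted p = 0.0334 (0.570, estimated correlation). Transcription regulator genes were higher, with 5 of 58 called higher and 0 lower (7 and 1 adjusted over the list alone). The regulator list had a camera adjusted p = 0.00546 (0.340, estimated correlation). Osmolyte genes were higher, with 1 of 8 called higher and 0 lower (3 and 0 adjusted over the list alone). The osmolyte list had a camera adjusted p = 0.0175 (0.515, estimated correlation). Transposase genes were higher, with 1 of 39 called higher and 0 lower (1 and 0 adjusted over the list alone). The transposase list had a camera adjusted p = 0.0175 (0.515, estimated correlation). Heterodisulfide reductases were higher, with 3 of 9 called higher and 0 lower (4 and 0 adjusted over the list alone). The heterodisulfide list had a camera adjusted p = 0.0334 (0.570, estimated correlation). The 3 reductase genes called, hdrA, hdrC and hdrB at Mbar_A1952 to Mbar_A1954, changed by 2.42 ± 0.62, 2.65 ± 0.67 and 2.59 ± 0.61. The heat shock gene Mbar_A1806 separated the fre libraries, at 1681, 12443 and 12334 CPM against 204 to 367 CPM in the parent.

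edgeR called 110 of 3072 genes tested, 69 higher and 41 lower. Of these, 50 of the higher and 20 of the lower genes moved by at least 1 log2 unit. The count was 25, 25 and 30 without parent replicates 1, 2 and 3 and 333, 24 and 21 without fre replicates 1, 2 and 3, 296 in a fit of the fre and parental libraries alone and 231 with DESeq2. Mbar_A2632 lost its call without parent replicates 1, 2 and 3 and fre replicates 2 and 3 (adjusted p up to 0.127). Mbar_A3428 lost its call without parent replicate 2 and fre replicate 3 (adjusted p up to 0.0687). Mbar_A0478 lost its call without parent replicate 1 and fre replicates 2 and 3 (adjusted p up to 0.0858). The hdrA and hdrC calls were lost without any 1 of the 6 libraries (adjusted p up to 0.149 and 0.138), and hdrB lost its call without parent replicates 1, 2 and 3 and fre replicate 3 (adjusted p up to 0.127).

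Without vhx, barely transcribed in the parent, a run of sugar nucleotide genes fell. Mbar_A2022 (glucosamine-fructose-6-phosphate aminotransferase), Mbar_A2021 (phosphoglucomutase) and Mbar_A2020 (glucose-1-phosphate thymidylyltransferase), neighbours at 2552095 to 2556521, changed by -3.63 ± 0.19, -3.26 ± 0.23 and -2.83 ± 0.25 (edgeR adjusted p = 1.58e-13, 1.20e-10 and 1.31e-08), with Mbar_A2022 falling from 397 ± 29.4 to 32.1 ± 3.99 CPM. Neighbouring stress genes fell: Mbar_A0825 (-2.82 ± 0.25, adjusted p = 1.16e-08) and Mbar_A0826 (-2.000 ± 0.37, adjusted p = 0.00284). So did the adjacent ferritin gene Mbar_A0827 (-2.28 ± 0.43, adjusted p = 0.00319). Another sugar nucleotide run, Mbar_A0034 (GDP-mannose 4,6-dehydratase), Mbar_A0035 and Mbar_A0036 (dTDP-glucose 4,6-dehydratase), rose by 1.66 ± 0.20, 1.48 ± 0.26 and 1.63 ± 0.21. The highest fold change belonged to the hypothetical gene Mbar_A2632 (5.11 ± 1.24, adjusted p = 0.0345).

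Phosphate uptake genes were lower as a list (median -1.58), with 0 of 5 called (5 adjusted over the list alone). Camera gave the phosphate list adjusted p = 0.000789 (0.552, estimated correlation). ATP synthase genes were lower as a list (median -0.68), with 0 of 18 called (0 adjusted over the list alone). Camera gave the ATP synthase list adjusted p = 0.0377 (0.681, estimated correlation). Chaperones and proteases were higher, with 1 of 19 called higher and 0 lower (9 and 0 adjusted over the list alone). The chaperone list had a camera adjusted p = 0.00253 (0.552, estimated correlation). Genes of carbon monoxide dehydrogenase and acetate use were higher as a list (median 0.47), with 0 of 17 called (0 adjusted over the list alone). The acetate list had a camera adjusted p = 0.00902 (0.552, estimated correlation). F420H2 dehydrogenase genes were higher, with 2 of 14 called higher and 0 lower (3 and 0 adjusted over the list alone). The fpo list had a camera adjusted p = 0.0192 (0.611, estimated correlation). Heterodisulfide reductases were higher as a list (median 0.54), with 0 of 9 called (4 adjusted over the list alone). Camera gave the heterodisulfide list adjusted p = 0.0216 (0.611, estimated correlation). The heat shock gene Mbar_A1806 read 249, 17754 and 13901 CPM in vhx, only replicate 1 near the parental range.

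The test called 87 of 3072 genes tested, 49 higher and 38 lower. Of these, 24 of the higher and 29 of the lower genes moved by at least 1 log2 unit. It called 32, 27 and 34 without parent replicates 1, 2 and 3 and 289, 34 and 25 without vhx replicates 1, 2 and 3, 213 in a fit of these strains alone and 232 with DESeq2. Without vhx replicate 1 they were 143 higher and 146 lower. Mbar_A2632 lost its call without parent replicates 1, 2 and 3 and vhx replicates 2 and 3 (adjusted p up to 0.144).

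The ech strain lacks the hydrogenase that couples ferredoxin to H2. In it the cation transporter gene Mbar_A0904 rose, from 374 ± 37.2 to 1245 ± 44.3 CPM (1.74 ± 0.36, edgeR adjusted p = 0.00581). DNA polymerase IV (Mbar_A2765), a lesion-bypass polymerase, rose by 2.08 ± 0.32 (adjusted p = 0.000254) and the hypothetical gene Mbar_A2435 by 1.95 ± 0.21 (adjusted p = 4.56e-07). Surface layer protein B (Mbar_A0809) changed by -1.15 ± 0.20 (adjusted p = 0.000909), glutamine synthetase (Mbar_A0666) by -0.94 ± 0.19 (adjusted p = 0.00458) and a hydrogenase maturation gene (Mbar_A1851) by -1.12 ± 0.22 (adjusted p = 0.00359). The 2 largest increases were in Mbar_A2864 (2.48 ± 0.71) and Mbar_A2085 (2.29 ± 0.66), both hypothetical, and the 3 largest decreases in the acetyltransferase gene Mbar_A0271 (-3.08 ± 0.81), ccdA (Mbar_A3428, -2.97 ± 0.75) and the serine O-acetyltransferase gene Mbar_A2421 (-2.79 ± 0.82). Without ech replicate 3, Mbar_A2085 (647 ± 732 CPM) was at 0.76 and Mbar_A2421 at -6.63, so 1 library carries their size and rank. The heat shock gene Mbar_A1806 stood at 550.1, 606 and 13157 CPM in the 3 ech libraries.

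edgeR called 228 of 3069 genes tested, 117 higher and 111 lower. Of these, 52 of the higher and 68 of the lower genes moved by at least 1 log2 unit. Of the 31 lists tested, camera called 0 (smallest adjusted p = 0.397), and 3 had an unadjusted p under 0.05. The count was 74, 87 and 73 without parent replicates 1, 2 and 3 and 132, 119 and 101 without ech replicates 1, 2 and 3, and 674 in a fit of the ech and parental libraries alone. Lower genes were in the majority with RLE size factors (110 higher, 120 lower), no low-count filter (82, 94) and DESeq2 (146, 150). Mbar_A2864 (adjusted p = 0.0400) lost its call without parent replicates 1 and 2 and ech replicates 1 and 2 (adjusted p up to 0.156). Mbar_A2085 (adjusted p = 0.0420) lost its call without parent replicates 1, 2 and 3 and ech replicate 3 (adjusted p up to 0.473). Mbar_A0271 (adjusted p = 0.0217) lost its call without parent replicate 1 and ech replicates 2 and 3 (adjusted p up to 0.0991). Mbar_A3428 (adjusted p = 0.0188) lost its call without parent replicate 2 and ech replicates 1 and 2 (adjusted p up to 0.0803). Mbar_A2421 (adjusted p = 0.0444) lost its call without parent replicates 1, 2 and 3 and ech replicates 1 and 2 (adjusted p up to 0.108).

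In the frh strain, which lacks the main F420-reducing hydrogenase by transcript level and by label carries attB where the parent has attP, there were higher transcripts of the F420H2 dehydrogenase (fpo), a membrane complex that oxidises reduced F420 and pumps protons. All 13 genes of the fpo operon (4364898 to 4375239) rose, and fpoD (Mbar_A3409) went from 124 ± 6.77 to 652 ± 29.4 CPM (2.39 ± 0.19, edgeR adjusted p = 2.29e-09). The separately located fpoF (Mbar_A0255, 304696 to 305736) was the 1 member of the list of 14 not called over all genes tested. Stress and iron storage genes fell together: Mbar_A0825 (-2.87 ± 0.25, adjusted p = 1.24e-08), Mbar_A0826 (-2.83 ± 0.38, adjusted p = 3.28e-05) and ferritin (Mbar_A0827, -2.86 ± 0.44, adjusted p = 0.000232). The cation transporter gene Mbar_A0904 fell from 374 ± 37.2 to 43.0 ± 2.86 CPM (-3.11 ± 0.40, adjusted p = 1.50e-05) and ccdA (Mbar_A3428) changed by -3.30 ± 0.72 (adjusted p = 0.00715). The genes just beyond ferritin, Mbar_A0828 (an Fe-S oxidoreductase), Mbar_A0829 and Mbar_A0830 (hypothetical), had the largest increases, 4.48 ± 1.16, 4.67 ± 1.31 and 4.63 ± 1.16 (adjusted p = 0.0256, 0.0403 and 0.0206), but spread widely between libraries (3927 ± 5145 CPM for Mbar_A0830) and were 2.18, 2.26 and 2.60 without frh replicate 1.

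Genes of the F420H2 dehydrogenase were higher, with 13 of 14 called higher and 0 lower (14 and 0 adjusted over the list alone). Camera gave the fpo list adjusted p = 1.54e-40 (4.17e-05, estimated correlation). The ribosomal protein genes were lower, with 0 of 61 called higher and 14 lower (0 and 30 adjusted over the list alone). Camera gave the ribosomal list adjusted p = 1.45e-15 (0.572, estimated correlation). Methyl oxidation genes were lower, with 0 of 30 called higher and 2 lower (0 and 2 adjusted over the list alone). Camera gave the methyl oxidation list adjusted p = 0.0413 (0.684, estimated correlation). RNA polymerase and translation factor genes were lower, with 1 of 36 called higher and 2 lower (1 and 6 adjusted over the list alone). The RNA polymerase list had a camera adjusted p = 0.0413 (0.684, estimated correlation). Aminoacyl-tRNA synthetases were lower (median -0.29), with 1 of 27 called higher and 0 lower (1 and 5 adjusted over the list alone). Camera gave the synthetase list adjusted p = 0.00588 (0.661, estimated correlation). Nitrogen fixation and ammonium genes were higher, with 4 of 27 called higher and 0 lower (4 and 0 adjusted over the list alone). The nitrogen list had a camera adjusted p = 0.00145 (0.572, estimated correlation). Genes of carbon monoxide dehydrogenase and acetate use were higher, with 1 of 17 called higher and 0 lower (1 and 0 adjusted over the list alone). Camera gave the acetate list adjusted p = 0.00588 (0.572, estimated correlation). Osmolyte genes were higher, with 1 of 8 called higher and 0 lower (2 and 0 adjusted over the list alone). Camera gave the osmolyte list adjusted p = 0.0462 (0.644, estimated correlation). With the length trend removed the methyl oxidation and osmolyte lists both had a camera adjusted p of 0.0509. The heat shock gene Mbar_A1806 stood at 903, 1932 and 11522 CPM in the 3 frh libraries.

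In all, 181 of 3071 genes tested, 103 higher and 78 lower, were called by edgeR. Of these, 72 of the higher and 35 of the lower genes moved by at least 1 log2 unit. The count was 76, 92 and 85 without parent replicates 1, 2 and 3 and 93 without frh replicate 2, and 279 with DESeq2 (132 higher, 147 lower). Without frh replicate 1 there were 91 higher and 92 lower. Mbar_A0828 lost its call without parent replicates 1, 2 and 3 and frh replicate 1 (adjusted p up to 0.196). Mbar_A0829 lost its call without parent replicates 1, 2 and 3 and frh replicates 1 and 2 (adjusted p up to 0.225). Mbar_A0830 lost its call without parent replicates 1, 2 and 3 and frh replicate 1 (adjusted p up to 0.124).

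**Figure D2:**
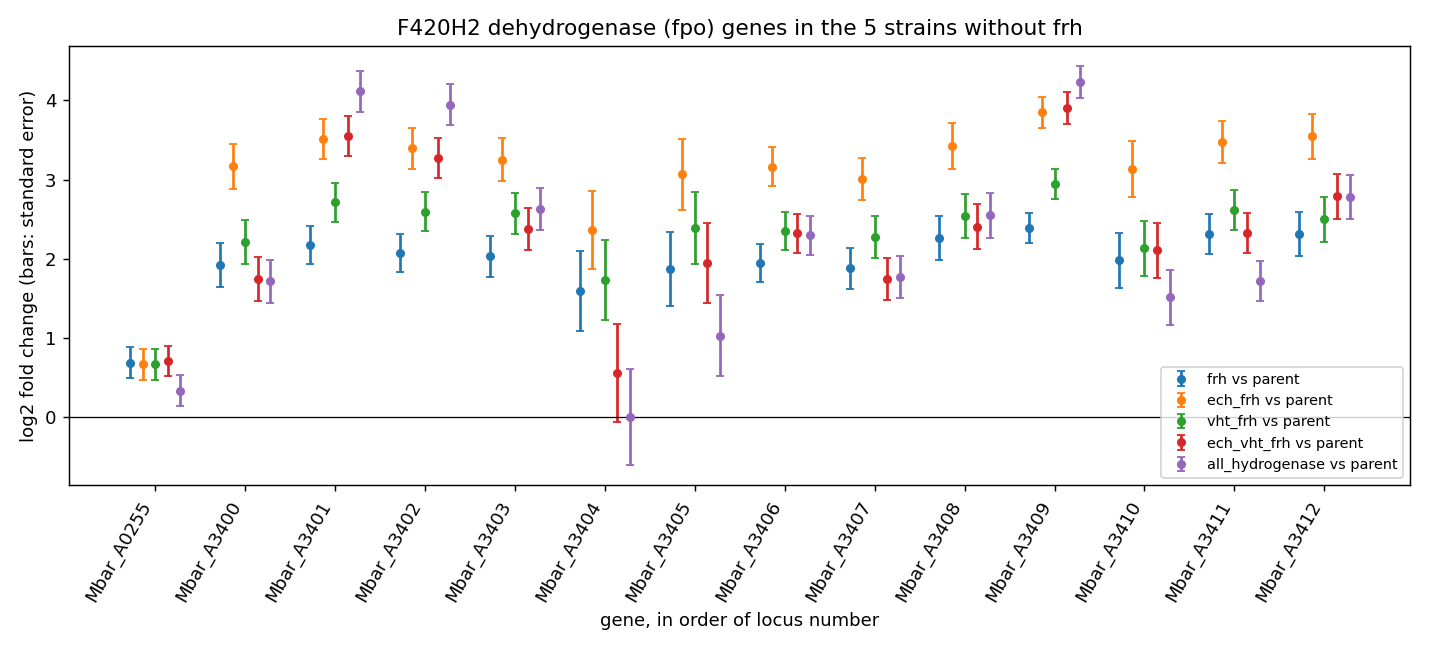
Log2 fold change against the parent of the 14 F420H2 dehydrogenase genes in the 5 strains without frh, with bars showing the standard error from edgeR. In fpoD (Mbar_A3409) the values run from 2.39 in frh to 4.24 in all_hydrogenase.

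In the ech_frh strain the fpo genes were also higher than in the parent, and all 14 were called. F420H2 dehydrogenase genes were higher, with 14 of 14 called higher and 0 lower (14 and 0 adjusted over the list alone). The fpo list had a camera adjusted p = 4.26e-74 (5.57e-07, estimated correlation). The fpoD gene reached 1794 ± 141 CPM (3.85 ± 0.20, edgeR adjusted p = 9.80e-14). The largest increases were in 3 adjacent copies of gvpA, which encodes the gas vesicle structural protein: Mbar_A0328 (4.66 ± 0.70, adjusted p = 0.000130), Mbar_A0327 (4.22 ± 0.63, adjusted p = 0.000132) and Mbar_A0326 (4.18 ± 0.57, adjusted p = 2.99e-05), at 385649 to 386407. Only 11.4% of the reads of Mbar_A0327 and of Mbar_A0328 were unique against 88.9% for Mbar_A0326, so the share of each copy is uncertain, and with unique reads the 3 changes were 3.99, 5.20 and 4.12. A formylmethanofuran dehydrogenase gene (Mbar_A1560) rose by 3.66 ± 0.58 (adjusted p = 0.000163) and the nitrogenase iron protein NifH (Mbar_A0171) by 2.36 ± 0.36 (adjusted p = 7.19e-05). The decreases were led by ccdA (Mbar_A3428, -3.91 ± 0.80, adjusted p = 0.00327, and -6.61 without ech_frh replicate 2), Mbar_A0825 (-3.03 ± 0.25, adjusted p = 1.17e-09), ferritin (Mbar_A0827, -2.71 ± 0.44) and Mbar_A0826 (-2.71 ± 0.38).

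Gas vesicle genes were higher, with 3 of 3 called higher and 0 lower (3 and 0 adjusted over the list alone). The gas vesicle list had a camera adjusted p = 2.07e-06 (0.0474, estimated correlation). Genes of nitrogen fixation and ammonium use were higher, with 7 of 27 called higher and 0 lower (7 and 0 adjusted over the list alone). Camera gave the nitrogen list adjusted p = 1.07e-06 (0.154, estimated correlation). Methylamine and methylsulfide methyltransferases were higher, with 2 of 11 called higher and 0 lower (2 and 0 adjusted over the list alone). The methylamine list had a camera adjusted p = 0.00368 (0.323, estimated correlation). Osmolyte genes were higher, with 1 of 8 called higher and 0 lower (1 and 0 adjusted over the list alone). The osmolyte list had a camera adjusted p = 0.0242 (0.354, estimated correlation). Ribosomal protein genes were lower, with 0 of 61 called higher and 6 lower (0 and 6 adjusted over the list alone). The ribosomal list had a camera adjusted p = 0.00581 (0.973, estimated correlation). Phosphate uptake genes were lower as a list (median -1.18), with 0 of 5 called (0 adjusted over the list alone). The phosphate list had a camera adjusted p = 0.0460 (0.738, estimated correlation). edgeR called 248 of 3065 genes tested, 149 higher and 99 lower. Of these, 87 of the higher and 61 of the lower genes moved by at least 1 log2 unit. There were 170 higher and 177 lower with DESeq2. The count was 98 and 107 without parent replicates 2 and 3, 85 higher and 31 lower without parent replicate 1, 101 (79 higher, 22 lower) and 127 without ech_frh replicates 1 and 3, 743 in a fit of these strains alone, and 156 with ech_frh replicate 1 and the library labelled ech_vht_frh replicate 3 both left out.

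The vht_frh strain lost nearly all reads of the plasmid. Its 20 plasmid genes summed to 9.31 ± 3.18 CPM against 474 ± 34.7 in the parent. The hypothetical genes Mbar_B3742 and Mbar_B3759 had 0 reads in the 3 vht_frh libraries, at least 66.3-fold and 62.4-fold lower than the parental 42.9 ± 7.41 and 40.4 ± 4.51 CPM against a floor of 3 reads over the group, and the partition gene parA (Mbar_B3749) changed by -7.47 ± 0.72 (edgeR adjusted p = 3.89e-08). On the chromosome the hypothetical gene Mbar_A1686 fell from 1578 ± 99.8 to 109.6 ± 15.4 CPM (-3.85 ± 0.70, adjusted p = 0.00137). The fpo genes were higher, with fpoD at 956 ± 56.9 CPM (2.94 ± 0.19, adjusted p = 2.78e-11). Nitrogenase genes rose, among them NifH (Mbar_A0171, 3.52 ± 0.37, adjusted p = 1.43e-07, 269 ± 87.3 against 23.3 ± 3.85 CPM), a P-II regulator (Mbar_A0169, 2.40 ± 0.36) and the molybdenum-iron protein alpha chain (Mbar_A0168, 2.31 ± 0.40). The alkaline phosphatase gene Mbar_A1231 had the largest increase (3.77 ± 0.92, adjusted p = 0.0159).

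Genes of the F420H2 dehydrogenase were higher, with 14 of 14 called higher and 0 lower (14 and 0 adjusted over the list alone). Camera gave the fpo list adjusted p = 4.32e-50 (1.00e-05, estimated correlation). Nitrogen fixation and ammonium genes were higher, with 15 of 27 called higher and 0 lower (17 and 0 adjusted over the list alone). The nitrogen list had a camera adjusted p = 3.41e-16 (0.00857, estimated correlation). Methylamine and methylsulfide methyltransferases were higher, with 3 of 11 called higher and 0 lower (3 and 0 adjusted over the list alone). Camera gave the methylamine list adjusted p = 0.0165 (0.348, estimated correlation). Genes of carbon monoxide dehydrogenase and acetate use were higher, with 3 of 17 called higher and 0 lower (3 and 0 adjusted over the list alone). The acetate list had a camera adjusted p = 0.0253 (0.382, estimated correlation). Gas vesicle genes were higher, with 2 of 3 called higher and 0 lower (3 and 0 adjusted over the list alone). Camera gave the gas vesicle list adjusted p = 0.0253 (0.348, estimated correlation). The 2 calls, in Mbar_A0327 and Mbar_A0328, held in 1 of 6 fits with a library left out, that without vht_frh replicate 3 (adjusted p up to 0.266 and 0.200), and the mostly unique copy Mbar_A0326 was not called (adjusted p = 0.102). With unique reads Mbar_A0327 was not called (adjusted p = 0.0967). Corrinoid genes were higher, with 4 of 33 called higher and 0 lower (5 and 0 adjusted over the list alone). The corrinoid list had a camera adjusted p = 0.0253 (0.348, estimated correlation). In the corrinoid list, methyltransferase corrinoid proteins are counted beside synthesis genes. The test called 203 of 3067 genes tested, 127 higher and 76 lower. Of these, 77 of the higher and 54 of the lower genes moved by at least 1 log2 unit. It called 123, 109 and 101 without parent replicates 1, 2 and 3 and 130, 124 and 113 without vht_frh replicates 1, 2 and 3, and 1096 in a fit of these strains alone. Mbar_A1231 lost its call without parent replicates 1, 2 and 3 (adjusted p up to 0.0762).

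In the ech_vht_frh strain the small heat shock protein gene Mbar_A1806 rose from 266 ± 88.7 to 27781 ± 21940.0 CPM (6.71 ± 1.68, edgeR adjusted p = 0.00309), and the CDC48 ATPase gene Mbar_A0908 rose by 5.42 ± 1.44 (adjusted p = 0.00467). The list of chaperones and proteases was not called (camera adjusted p = 0.486). Within the strain Mbar_A1806 read 33265 and 46458 CPM in replicates 1 and 2 and 3619 in the library labelled ech_vht_frh replicate 3. Mbar_A2197, which has no product in the file, rose by 5.47 ± 0.54 (adjusted p = 9.39e-08), the regulator gene Mbar_A1224 by 4.54 ± 0.62, the formylmethanofuran dehydrogenase gene Mbar_A1560 by 4.01 ± 0.59 and fpoD (Mbar_A3409) by 3.91 ± 0.20, to 1868 ± 167 CPM. In the remaining F420 hydrogenase operon freA (Mbar_A2287) rose by 1.56 ± 0.31 (adjusted p = 0.000248) and freG (Mbar_A2289) by 1.16 ± 0.26 (adjusted p = 0.000954), while freB (Mbar_A2290) read 52.0 ± 10.9 against 52.3 ± 7.42 CPM. Mbar_A1842 rose by 2.41 ± 0.37 (adjusted p = 1.81e-05). Ferredoxin (Mbar_A0736) changed by -4.58 ± 0.87 (adjusted p = 0.000126, and -8.10 without ech_vht_frh replicate 2), ribosomal protein S17e (Mbar_A1149) by -3.63 ± 0.45 and the stress protein gene Mbar_A0825 by -3.42 ± 0.26. The 20 plasmid genes summed to 25.4 and 34.2 CPM in replicates 1 and 2 (2 and 13 unique reads) and 239.8 in the library labelled ech_vht_frh replicate 3, against 474 ± 34.7 in the parent, and the transposase gene Mbar_B3755 among them changed by -4.42 ± 0.74 (adjusted p = 2.68e-05). The lowest fold change, in the hypothetical gene Mbar_A0521 (-5.27 ± 1.89, adjusted p = 0.0273), lost its call without parent replicate 3 and ech_vht_frh replicates 1, 2 and 3 (adjusted p up to 0.0856).

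F420H2 dehydrogenase genes were higher, with 13 of 14 called higher and 0 lower (13 and 0 adjusted over the list alone). The fpo list had a camera adjusted p = 2.77e-14 (0.0245, estimated correlation). Genes of nitrogen fixation and ammonium use were higher, with 18 of 27 called higher and 1 lower (18 and 1 adjusted over the list alone). Camera gave the nitrogen list adjusted p = 0.000149 (0.412, estimated correlation). Genes of carbon monoxide dehydrogenase and acetate use were higher, with 8 of 17 called higher and 1 lower (9 and 1 adjusted over the list alone). Camera gave the acetate list adjusted p = 0.0212 (0.412, estimated correlation). Methylamine and methylsulfide methyltransferases were higher, with 6 of 11 called higher and 0 lower (6 and 0 adjusted over the list alone). The methylamine list had a camera adjusted p = 0.0236 (0.412, estimated correlation). Osmolyte genes were higher, with 5 of 8 called higher and 0 lower (5 and 0 adjusted over the list alone). Camera gave the osmolyte list adjusted p = 0.0376 (0.412, estimated correlation). Phosphate uptake genes were lower, with 0 of 5 called higher and 5 lower (0 and 5 adjusted over the list alone). Camera gave the phosphate list adjusted p = 0.0236 (0.540, estimated correlation). The ribosomal protein genes were lower, with 13 of 61 called higher and 31 lower (13 and 31 adjusted over the list alone). Camera gave the ribosomal list adjusted p = 0.0212 (0.829, estimated correlation). RNA polymerase and translation factor genes were lower, with 6 of 36 called higher and 18 lower (6 and 18 adjusted over the list alone). Camera gave the RNA polymerase list adjusted p = 0.0415 (0.540, estimated correlation). Genes under 300 bp had a median of -0.63 here against 0.11 for those of 1000 bp or more, and with the length trend removed the ribosomal and RNA polymerase lists were no longer called (camera adjusted p = 0.283 and 0.196), nor was the osmolyte list (0.0528). edgeR called 1425 of 3061 genes tested, 716 higher and 709 lower. Of these, 493 of the higher and 493 of the lower genes moved by at least 1 log2 unit. No library left out moved this count by over 1.5 times (1143 to 1536 genes), but lower genes were in the majority without the library labelled ech_vht_frh replicate 3 (742 higher, 794 lower) and with no low-count filter (670, 776).

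**Figure D3:**
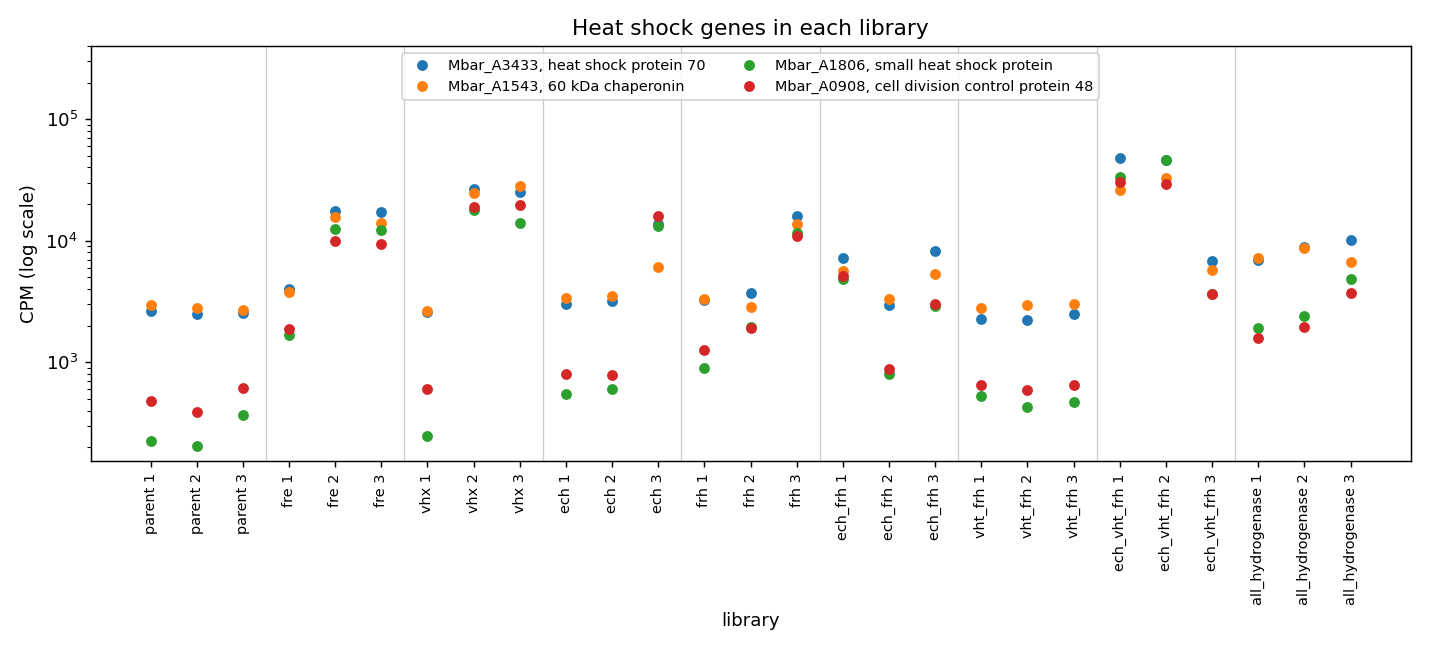
CPM (log axis) of 4 heat shock genes in each of the 27 libraries, grouped by strain. Libraries of 1 strain differed: Mbar_A1806 stood at 249 CPM in vhx replicate 1 and 17754 in replicate 2, and at 33265 in ech_vht_frh replicate 1 and 3619 in the library labelled replicate 3.

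The strain without any hydrogenase operon had the largest set of changed genes among the 8 comparisons with the parent. The neighbours Mbar_A0828 (Fe-S oxidoreductase), Mbar_A0829 and Mbar_A0830 (hypothetical), at 1003533 to 1005920, rose by 6.43 ± 1.23, 6.41 ± 1.41 and 6.89 ± 1.28 (edgeR adjusted p = 0.000219, 0.000829 and 0.000169), and Mbar_A0830 reached 18812 ± 15685 CPM. Acetolactate synthase (Mbar_A0438), of branched-chain amino acid synthesis, rose by 5.20 ± 0.93 (adjusted p = 0.000117), fpoD (Mbar_A3409) by 4.24 ± 0.20 (adjusted p = 1.38e-14), to 2344 ± 136 CPM, and DNA polymerase IV (Mbar_A2765) by 4.03 ± 0.34 (adjusted p = 7.17e-10). Transcripts of 3 genes fell to 0 reads over the group: the transposase gene Mbar_A1410 and the hypothetical genes Mbar_A2600 and Mbar_A2088 were at least 18.6-fold, 15.5-fold and 12.6-fold lower than the parental 15.7 ± 1.17, 13.04 ± 2.51 and 10.6 ± 4.34 CPM. Ribosomal protein S17e (Mbar_A1149) changed by -5.21 ± 0.49 (adjusted p = 7.00e-09), L39e (Mbar_A0457) by -4.88 ± 0.43 (adjusted p = 1.00e-09) and an archaeal histone (Mbar_A1584) by -4.91 ± 0.44 (adjusted p = 1.50e-09, 3.43 ± 1.68 against 104 ± 7.70 CPM).

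Camera called 1 list. Genes of the F420H2 dehydrogenase were higher, with 11 of 14 called higher and 0 lower (11 and 0 adjusted over the list alone). Camera gave the fpo list adjusted p = 3.73e-10 (0.0684, estimated correlation). The ribosomal list was not called (camera adjusted p = 0.567). edgeR called 1703 of 3053 genes tested, 808 higher and 895 lower. Of these, 555 of the higher and 694 of the lower genes moved by at least 1 log2 unit. Between 1502 and 1669 genes were called with 1 library left out, and no library moved the count by over 1.5 times. With the length trend removed 877 were higher and 770 lower. This strain was alone in its lane, so lane and genotype cannot be told apart.

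Gas vesicle and fpo transcripts were higher in ech_frh than in frh, a comparison within a lane that by label also carries pac-hpt. The gvpA copies Mbar_A0326, Mbar_A0327 and Mbar_A0328 rose by 4.03 ± 0.56, 3.25 ± 0.59 and 4.66 ± 0.69 (edgeR adjusted p = 0.000106, 0.00294 and 0.000361), Mbar_A1560 by 3.52 ± 0.58 (adjusted p = 0.000702) and fpoD (Mbar_A3409) by 1.46 ± 0.18 (adjusted p = 6.77e-06). Phosphate acetyltransferase (Mbar_A1821) was the 1 gene called lower (-1.03 ± 0.23, adjusted p = 0.0144), a call lost without frh replicates 1 and 2 and ech_frh replicates 1 and 3 (adjusted p up to 0.254). F420H2 dehydrogenase genes were higher, with 10 of 14 called higher and 0 lower (12 and 0 adjusted over the list alone). The fpo list had a camera adjusted p = 4.28e-28 (0.000524, estimated correlation). Gas vesicle genes were higher, with 3 of 3 called higher and 0 lower (3 and 0 adjusted over the list alone). The gas vesicle list had a camera adjusted p = 2.23e-12 (0.00158, estimated correlation). Ribosomal protein genes were higher as a list (median 0.35), with 0 of 61 called (0 adjusted over the list alone). The ribosomal list had a camera adjusted p = 1.08e-08 (0.435, estimated correlation). Nitrogen fixation and ammonium genes were higher, with 1 of 27 called higher and 0 lower (3 and 0 adjusted over the list alone). The nitrogen list had a camera adjusted p = 0.0126 (0.435, estimated correlation). Methylamine and methylsulfide methyltransferases were higher, with 1 of 11 called higher and 0 lower (1 and 0 adjusted over the list alone). Camera gave the methylamine list adjusted p = 0.0131 (0.435, estimated correlation). Aminoacyl-tRNA synthetases were higher as a list (median 0.16), with 0 of 27 called (0 adjusted over the list alone). The synthetase list had a camera adjusted p = 0.0131 (0.435, estimated correlation). Genes of the cofactor synthesis list were higher, with 1 of 23 called higher and 0 lower (4 and 0 adjusted over the list alone). The 1 call is Mbar_A1560, a formylmethanofuran dehydrogenase gene, and it is also the 1 call of the methyl oxidation list. Camera gave the cofactor list adjusted p = 0.0165 (0.249, estimated correlation). Methyl oxidation genes were higher, with 1 of 30 called higher and 0 lower (1 and 0 adjusted over the list alone). The methyl oxidation list had a camera adjusted p = 0.0165 (0.435, estimated correlation). Oxygen and redox stress genes were lower as a list (median -0.28), with 0 of 16 called (1 adjusted over the list alone). The redox stress list had a camera adjusted p = 0.0198 (0.449, estimated correlation). Heterodisulfide reductases were lower as a list (median -0.63), with 0 of 9 called (0 adjusted over the list alone). The heterodisulfide list had a camera adjusted p = 0.0247 (0.480, estimated correlation). In total 22 of 3065 genes tested, 21 higher and 1 lower, were called, with 258 at an unadjusted p under 0.05. The count was 14 and 36 without frh replicates 2 and 3, and 43 with DESeq2, and lower genes were 11 of the 36 and 9 of the 43. Mbar_A1806 read 4866, 799 and 2891 CPM in the ech_frh libraries against 903, 1932 and 11522 in frh.

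Plasmid genes were lower in vht_frh, which by label has FRT at vht, than in frh. In vht_frh Mbar_B3742 and Mbar_B3759 had 0 reads against 52.2 ± 7.38 and 66.9 ± 39.4 CPM in frh, and parA (Mbar_B3749) changed by -7.03 ± 0.74 (edgeR adjusted p = 8.25e-07). NifH (Mbar_A0171) rose from 66.2 ± 29.1 to 269 ± 87.3 CPM (2.005 ± 0.33, adjusted p = 0.000527). Genes of nitrogen fixation and ammonium use were higher, with 6 of 27 called higher and 0 lower (12 and 0 adjusted over the list alone). Camera gave the nitrogen list adjusted p = 1.43e-10 (0.0521, estimated correlation). Transposase genes were lower, with 0 of 39 called higher and 2 lower (0 and 2 adjusted over the list alone). Camera gave the transposase list adjusted p = 0.000182 (0.203, estimated correlation). The transposase list includes 4 plasmid genes. The ribosomal protein genes were higher as a list (median 0.40), with 0 of 61 called (1 adjusted over the list alone). Camera gave the ribosomal list adjusted p = 1.89e-11 (0.291, estimated correlation). Genes of the F420H2 dehydrogenase were higher as a list (median 0.35), with 0 of 14 called (0 adjusted over the list alone). Camera gave the fpo list adjusted p = 0.00242 (0.293, estimated correlation). Gas vesicle genes were higher as a list (median 1.49), with 0 of 3 called (3 adjusted over the list alone). Camera gave the gas vesicle list adjusted p = 0.00507 (0.203, estimated correlation). Methyl oxidation genes were higher as a list (median 0.40), with 0 of 30 called (7 adjusted over the list alone). Camera gave the methyl oxidation list adjusted p = 0.000174 (0.203, estimated correlation). Aminoacyl-tRNA synthetases were higher as a list (median 0.23), with 0 of 27 called (0 adjusted over the list alone). Camera gave the synthetase list adjusted p = 0.00159 (0.293, estimated correlation). Corrinoid genes were higher, with 1 of 33 called higher and 0 lower (2 and 0 adjusted over the list alone). Camera gave the corrinoid list adjusted p = 0.00648 (0.203, estimated correlation). Genes of formate, ferredoxin and F420 redox carriers were higher as a list (median 0.16), with 0 of 37 called (1 adjusted over the list alone). The redox carrier list had a camera adjusted p = 0.00972 (0.0521, estimated correlation). Cofactor synthesis genes were higher as a list (median 0.20), with 0 of 23 called (7 adjusted over the list alone). The cofactor list had a camera adjusted p = 0.0123 (0.203, estimated correlation). In total 23 of 3067 genes tested, 8 higher and 15 lower, were called, and 5 higher and 16 lower with RLE size factors, with 337 at an unadjusted p under 0.05. The count was 42 without frh replicate 1 and 15 without vht_frh replicate 2, and 56 with DESeq2. Higher and lower were 25 and 17 without frh replicate 1, which turns the majority, 3 and 15 without frh replicate 2, and 1 and 14 without vht_frh replicate 2. Mbar_A1806 read 528, 425 and 473 CPM in vht_frh.

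The whole fpo list was higher in ech_frh than in ech. The fpoH gene (Mbar_A3408) went from 31.2 ± 5.30 to 367 ± 26.5 CPM (3.56 ± 0.30, edgeR adjusted p = 1.54e-09). F420H2 dehydrogenase genes were higher, with 14 of 14 called higher and 0 lower (14 and 0 adjusted over the list alone). The fpo list had a camera adjusted p = 1.59e-135 (1.77e-09, estimated correlation). The gvpA copies Mbar_A0326, Mbar_A0327 and Mbar_A0328 rose by 4.46 ± 0.61, 4.67 ± 0.71 and 4.23 ± 0.71, and NifH (Mbar_A0171) by 4.29 ± 0.45 (adjusted p = 1.63e-07). The cation transporter gene Mbar_A0904 fell from 1245 ± 44.3 to 102 ± 10.9 CPM (-3.60 ± 0.40, adjusted p = 1.01e-06) and Mbar_A0825 changed by -3.29 ± 0.25 (adjusted p = 5.80e-10). Gas vesicle genes were higher, with 3 of 3 called higher and 0 lower (3 and 0 adjusted over the list alone). The gas vesicle list had a camera adjusted p = 1.55e-11 (0.00267, estimated correlation). Nitrogen fixation and ammonium genes were higher, with 4 of 27 called higher and 0 lower (9 and 0 adjusted over the list alone). The nitrogen list had a camera adjusted p = 5.18e-10 (0.0424, estimated correlation). Methylamine and methylsulfide methyltransferases were higher, with 1 of 11 called higher and 0 lower (2 and 0 adjusted over the list alone). The methylamine list had a camera adjusted p = 0.00274 (0.272, estimated correlation). Aminoacyl-tRNA synthetases were lower as a list (median -0.22), with 0 of 27 called (0 adjusted over the list alone). The synthetase list had a camera adjusted p = 0.00851 (0.469, estimated correlation). edgeR called 41 of 3065 genes tested, 30 higher and 11 lower.

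Between ech_vht_frh and vht_frh, again within a lane, the heat shock gene Mbar_A1806 rose by 5.87 ± 1.61 (edgeR adjusted p = 0.01005) and Mbar_A0908 by 5.07 ± 1.41 (adjusted p = 0.0110), while the list of chaperones and proteases was not called (camera adjusted p = 0.248). The formylmethanofuran dehydrogenase gene Mbar_A1560 rose by 4.94 ± 0.65 (adjusted p = 1.18e-05), freA (Mbar_A2287) by 1.64 ± 0.31 (adjusted p = 0.000358) and fpoD (Mbar_A3409) by 0.97 ± 0.18 (adjusted p = 0.000230). Phosphate acetyltransferase (Mbar_A1821) changed by -1.92 ± 0.24 (adjusted p = 2.52e-06) and a phosphatidyltransferase gene (Mbar_A1250) by -2.68 ± 0.43 (adjusted p = 7.59e-05). The plasmid genes Mbar_B3742 and Mbar_B3759 were called higher against 0 reads, calls lost without the library labelled ech_vht_frh replicate 3 (adjusted p = 0.163 and 0.169). F420 hydrogenase genes were higher, with 5 of 8 called higher and 0 lower (6 and 0 adjusted over the list alone). The F420 hydrogenase list had a camera adjusted p = 0.0166 (0.892, estimated correlation). By product text this list takes in vhx genes. Heterodisulfide reductases were higher, with 6 of 9 called higher and 0 lower (7 and 1 adjusted over the list alone). Camera gave the heterodisulfide list adjusted p = 0.0376 (0.892, estimated correlation). Phosphate uptake genes were lower, with 0 of 5 called higher and 5 lower (0 and 5 adjusted over the list alone). The phosphate list had a camera adjusted p = 0.0166 (0.892, estimated correlation). RNA polymerase and translation factor genes were lower, with 4 of 36 called higher and 15 lower (4 and 16 adjusted over the list alone). The RNA polymerase list had a camera adjusted p = 0.0376 (0.892, estimated correlation). With the length trend removed it was 0.327. Surface layer genes were lower, with 1 of 12 called higher and 6 lower (1 and 7 adjusted over the list alone). The surface layer list had a camera adjusted p = 0.0376 (0.247, estimated correlation). The test called 996 of 3061 genes tested, 518 higher and 478 lower, but 573 higher and 610 lower without the library labelled ech_vht_frh replicate 3 and 441 and 517 with no low-count filter. The count was 600 and 569 without ech_vht_frh replicates 1 and 2.

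Against ech_frh, the ech_vht_frh strain had higher transcripts of Mbar_A2197 (4.17 ± 0.50, edgeR adjusted p = 8.53e-06) and the regulator genes Mbar_A1065 (3.54 ± 0.81, adjusted p = 0.00430) and Mbar_A1224 (3.51 ± 0.58, adjusted p = 0.000293). The plasmid transposase gene Mbar_B3755 changed by -3.75 ± 0.78 (adjusted p = 0.00126), Mbar_A1250 by -2.51 ± 0.44 and S17e (Mbar_A1149) by -2.34 ± 0.45 (adjusted p = 0.000701, and -3.81 without the library labelled ech_vht_frh replicate 3). Genes of the F420H2 dehydrogenase were lower, with 0 of 14 called higher and 9 lower (0 and 10 adjusted over the list alone). Camera gave the fpo list adjusted p = 0.00126 (0.583, estimated correlation). Heterodisulfide reductases were higher, with 4 of 9 called higher and 0 lower (4 and 0 adjusted over the list alone). The heterodisulfide list had a camera adjusted p = 0.0255 (0.697, estimated correlation). In total 764 of 3061 genes tested, 408 higher and 356 lower, were called. The count was 494 and 488 without ech_frh replicates 2 and 3 and 374 and 359 without ech_vht_frh replicates 1 and 2, and 248 in a fit of these strains alone (196 higher, 52 lower). Lower genes were in the majority without the library labelled ech_vht_frh replicate 3 (522 higher, 566 lower) and with no low-count filter (360, 394).

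By label all_hydrogenase lacks vhx, fre, Mbar_A1842 and Mbar_A1843 beyond ech_vht_frh and carries pac-hpt in place of FRT at ech and no marker in place of FRT at vht. Between them Mbar_A0828 to Mbar_A0830 rose, by 4.69 ± 1.13, 5.47 ± 1.36 and 4.67 ± 1.16 (edgeR adjusted p = 0.00972, 0.0115 and 0.0114). These calls were lost for Mbar_A0828 without ech_vht_frh replicate 2 (adjusted p up to 0.0531), for Mbar_A0829 without ech_vht_frh replicate 2 (adjusted p up to 0.0579) and for Mbar_A0830 without ech_vht_frh replicate 2 (adjusted p up to 0.0533). Mbar_B3757, on the plasmid that was low in ech_vht_frh, rose by 4.40 ± 0.67 (adjusted p = 0.000103) and valyl-tRNA synthetase (Mbar_A1976) by 1.09 ± 0.17. Mbar_A1560 changed by -3.60 ± 0.59 (adjusted p = 0.000260), glutamine synthetase (Mbar_A0666) by -1.20 ± 0.20 and the ammonium transporter gene Mbar_A0158 by -1.92 ± 0.34. Aminoacyl-tRNA synthetases were higher, with 11 of 27 called higher and 0 lower (14 and 1 adjusted over the list alone). Camera gave the synthetase list adjusted p = 0.000174 (0.523, estimated correlation). Ribosomal protein genes were higher, with 8 of 61 called higher and 1 lower (13 and 4 adjusted over the list alone). The ribosomal list had a camera adjusted p = 0.0165 (0.903, estimated correlation). Phosphate uptake genes were higher as a list (median 1.39), with 0 of 5 called (0 adjusted over the list alone). Camera gave the phosphate list adjusted p = 0.0312 (0.841, estimated correlation). Genes of nitrogen fixation and ammonium use were lower, with 1 of 27 called higher and 11 lower (2 and 14 adjusted over the list alone). Camera gave the nitrogen list adjusted p = 0.000248 (0.523, estimated correlation). The test called 452 of 3053 genes tested, 229 higher and 223 lower. The count was 214 without ech_vht_frh replicate 2 and 264 without all_hydrogenase replicate 2, and 72 in a fit of these strains alone (30 higher, 42 lower). Lower genes were also in the majority with RLE size factors (213, 240), a filter at 10 CPM (225, 233) and DESeq2 (254, 304), and without ech_vht_frh replicates 1 (185, 250) and 2 (90, 124) or all_hydrogenase replicate 2 (149 lower of 264).

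An interaction term asked whether ech loss acted differently without frh. By label ech_frh has pac-hpt at ech and ech no marker. Lanes of ech and the parent differ, so lane does not cancel. Mbar_A1285 (hypothetical, 2.62 ± 0.46, edgeR adjusted p = 0.00561) and the iron(III) dicitrate-binding protein gene Mbar_A1870 (2.33 ± 0.44, adjusted p = 0.00996) stood higher in ech_frh than the 2 single losses add up to, and Mbar_A2435 (-1.98 ± 0.28, adjusted p = 0.000487) and Mbar_A0034 (-1.76 ± 0.28, adjusted p = 0.00166) lower. In total 16 of 3065 genes tested, 9 higher and 7 lower, were called, with 342 at an unadjusted p under 0.05. Without ech replicate 2 they were 3 higher and 4 lower, without frh replicate 3 5 and 7, and without ech replicate 3 17 and 6. The count was 8, 7 and 6 without parent replicates 1, 2 and 3, 10 and 7 without ech replicates 1 and 2, 8 without frh replicate 2 and 33 and 4 without ech_frh replicates 1 and 2, 39 with the strains concerned alone, 61 with DESeq2, and 53 with ech_frh replicate 1 and the library labelled ech_vht_frh replicate 3 both left out.

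The same question for ech and vht was asked among strains without frh, where both differences lie within a lane, so a shift between lanes cancels. The gvpA copy Mbar_A0328 lay below the sum of the separate losses (-4.22 ± 0.93, edgeR adjusted p = 0.00775), and so did Mbar_A0327 (-3.02 ± 0.82, adjusted p = 0.0214), a call lost without frh replicate 2, ech_frh replicates 2 and 3, vht_frh replicate 2 and ech_vht_frh replicate 2 (adjusted p up to 0.0844). Both hold 11.4% unique reads. The copy with 88.9%, Mbar_A0326, stood at -2.71 ± 0.75 (adjusted p = 0.0240) and lost its call without frh replicate 2, ech_frh replicates 2 and 3, vht_frh replicates 1 and 2 and ech_vht_frh replicate 1 (adjusted p up to 0.0672). The heat shock gene Mbar_A1806 lay above that sum by 6.62 ± 2.02 (adjusted p = 0.0404) and the Lon protease gene Mbar_A2576 by 7.01 ± 2.01 (adjusted p = 0.0315). Mbar_A1806 lost its call without frh replicates 2 and 3, ech_frh replicates 2 and 3, vht_frh replicates 1, 2 and 3 and ech_vht_frh replicates 1 and 2 (adjusted p up to 0.118). Mbar_A2576 lost its call without frh replicate 3, ech_frh replicates 2 and 3, vht_frh replicates 1, 2 and 3 and ech_vht_frh replicates 1 and 2 (adjusted p up to 0.136), and was at 4.16 without frh replicate 3. In total 370 of 3061 genes tested, 208 higher and 162 lower, were called. Lower genes were in the majority without the library labelled ech_vht_frh replicate 3 (356 higher, 432 lower), without vht_frh replicate 2 (102, 103) and with no low-count filter (143, 164). The count was 239 without frh replicate 2, 171 and 171 without ech_frh replicates 2 and 3, 194 and 205 without vht_frh replicates 1 and 2 and 145, 103 and 788 without ech_vht_frh replicates 1, 2 and 3, 211 with the strains concerned alone, and 811 with the doubted pair of libraries, ech_frh replicate 1 and the library labelled ech_vht_frh replicate 3, both left out.

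Over all 36 pairs of strains, the number of genes called by edgeR ran from 22 between ech_frh and frh to 1749 between all_hydrogenase and fre. The authors' deposited table holds, for each strain, a p-value per gene against the parent, which is under 0.05 for 549 genes in fre, 531 in vhx, 609 in ech, 553 in frh, 623 in ech_frh, 491 in vht_frh, 1631 in ech_vht_frh and 1702 in all_hydrogenase. Every gene called here for a strain has a fold change of the same sign in the authors' deposited table.

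**Figure D4:**
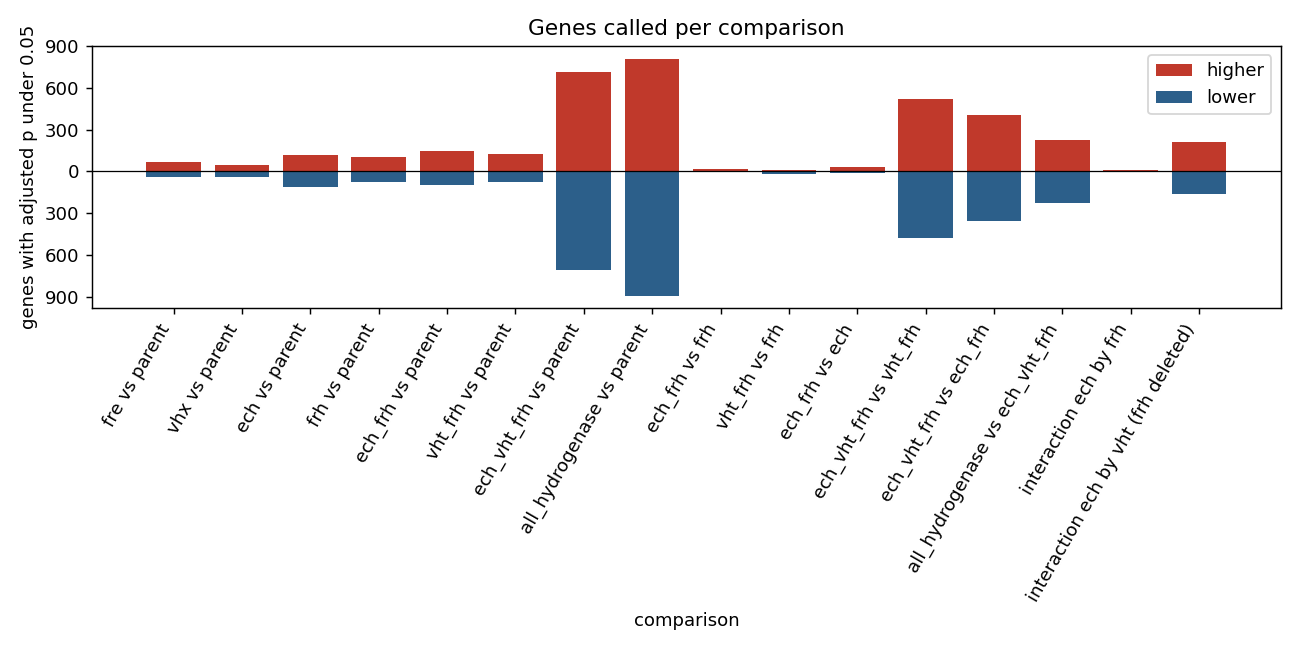
Genes called by edgeR at an adjusted p under 0.05 in each of the 16 comparisons, higher above the zero line and lower below it. The comparisons of ech_vht_frh and all_hydrogenase with the parent, with 1425 and 1703 genes, stand above the other 6 comparisons with the parent, which run from 87 to 248 in this fit of 27 libraries. In fits of only the strains compared the gap narrows, to 1364 and 1629 genes against 674 in ech, 743 in ech_frh and 1096 in vht_frh.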

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

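The tests of technical explanations in this part were chosen only after the results were seen. The counts of the interactions and the other splits of the samples were planned.

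Differences between backgrounds drew attention in both interactions. The effect of losing ech differed between strains with and without frh in 16 genes. In 6 of 100 splits, the real one included, as many were called, with up to 37 in another. The effect of losing ech among strains without frh differed with vht in 370 genes. In 2 of 100 splits, the real one included, as many were called, with up to 371 in another. The splits mix strains that differ in other ways, so neither share excludes chance. The count with vht ran from 103 to 788 with 1 library left out.

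In the library labelled ech_vht_frh replicate 3, vht reads stood at 62.0% of ech_frh replicate 1, frh at 71.0%, ech at 68.4% and plasmid genes at 61.2%. RNA or reads of ech_frh replicate 1 here would bring these at about the same share. Reads of ech cannot tell, at 71.8 CPM here and 25.4 and 161 in replicates 1 and 2. The frh over vht share was 1.15, so such a mixture is a candidate explanation. With the rest like replicates 1 and 2 it is argued against, as each of 4 heat shock genes stood at 49.2% or less of the level then expected, so the rest of the library would have to differ from both replicates, which was not tested. A whole ech_frh library under the wrong label is argued against: over 165 genes that separate the strains, the median share toward ech_frh was 72.7% (67.5 to 76.5%), against 84.97, 101.0 and 100.02% for ech_frh libraries left out in turn. Cells of this strain that kept vht are argued against as the whole cause, since they would bring no frh reads, yet frh stood at 4.17% of the parent against at most 0.0232% in replicates 1 and 2, and stay open beside another source of reads.

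More genes changed against the parent in ech_vht_frh and all_hydrogenase than in the other strains, but the gap narrows in fits of only the strains compared, to 1364 and 1629 genes against 1096 in vht_frh, 743 in ech_frh and 674 in ech. Sequencing lane as the cause is argued against for ech_vht_frh by 996 genes called against vht_frh in the same lane, but for all_hydrogenase, with 1703 genes, lane and strain cannot be told apart because the strain was alone in its lane. Gene length as the whole cause is argued against, since 1389 and 1647 genes were called with the length trend removed. Transcription of whole operons as the entire cause is argued against by the correlation of log2 fold changes between adjacent genes, 0.546 (0.456 to 0.623) and 0.308 (0.209 to 0.405), where the other 6 strains gave 0.783 or more. A response of the cells to losing several hydrogenases stays open, untested, as does a difference in RNA handling, with which the lower medians of genes under 300 bp, -0.63 and -0.40, would go.

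The plasmid genes were near 0 in vht_frh, and low in ech_vht_frh replicates 1 and 2 (25.4 and 34.2 CPM), where these tests were not run. In vht_frh reads shared with chromosomal copies are argued against, as unique plasmid reads stood at 1.30% of the parental level. Low depth is argued against too, since at the parental share each vht_frh library would hold at least 591 unique plasmid reads, and the highest held 11. Loss of the plasmid from most cells may account for this, but the 11 reads cannot be told apart from a plasmid that is kept and scarcely transcribed.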

How the results depend on the processing

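The length trend and the joint removal of a pair of libraries were chosen only after the results were seen; the other alternatives were planned.

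All 16 gene counts stayed within 1.5 times their value with RLE size factors, no low-count filter, a filter at 10 CPM, rRNA and tRNA kept, deleted genes removed, unique reads and the length trend removed. In a fit of only the strains compared, 9 moved: fre 296, vhx 213, ech 674, ech_frh 743 and vht_frh 1096 against the parent, 248 for ech_vht_frh against ech_frh, 72 for all_hydrogenase against ech_vht_frh, and 39 and 211 for the interactions of ech with frh and with vht. With DESeq2, 6 moved: fre 231, vhx 232 and frh 279 against the parent, 43 for ech_frh and 56 for vht_frh against frh, and 61 for the interaction of ech with frh. With ech_frh replicate 1 and the library labelled ech_vht_frh replicate 3 both left out, 3 of 9 moved: ech_frh against the parent to 156, and the interactions to 53 and 811. In 12 of the 16 comparisons the larger of the higher and lower sets changed under some setting. The cause of these moves was not tested. The fit of 27 libraries pools dispersion over strains.

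With each library left out in turn, the counts against the parent ranged from 21 to 333 for fre, 25 to 289 for vhx, 73 to 132 for ech, 76 to 183 for frh, 98 to 175 for ech_frh, 101 to 130 for vht_frh, 1143 to 1536 for ech_vht_frh and 1502 to 1669 for all_hydrogenase. They ranged from 14 to 36 for ech_frh and 15 to 42 for vht_frh against frh, 31 to 47 for ech_frh against ech, 569 to 1183 for ech_vht_frh against vht_frh, 359 to 1088 for ech_vht_frh against ech_frh, 214 to 496 for all_hydrogenase against ech_vht_frh, 4 to 33 for the interaction of ech with frh and 103 to 788 for that with vht.

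Of 14391 values of 894 named gene results under the alternatives, 12627 kept direction and call, 1763 lost the call (1434 of 5862 with a library left out, 329 of 8529 otherwise) and 1 reversed: the gvpA copy Mbar_A0328 in all_hydrogenase, 2.14 against the parent, was -0.50 with unique reads, which are 11.4% of its reads. Of 435 list tests camera called 82, 11 with an estimated correlation and 77 with the length trend removed. RLE size factors lowered the share of higher genes among those called in vht_frh against frh from 34.8 to 23.8%. At the depth here 3 reads in a library correspond to 1.49 to 4.79 CPM before TMM scaling.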

Other observations

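No test of an explanation is reported in this part; the splits of the samples were planned.

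Heat shock transcripts varied between libraries of a strain in ways that the labels do not name. The heat shock protein 70 gene Mbar_A3433 read 2485 to 2629 CPM in the parent and 2212 to 2471 CPM in vht_frh, but 3012, 3206 and 13724 in the 3 ech libraries and 3227, 3694 and 15907 in the 3 frh libraries. The 60 kDa chaperonin gene Mbar_A1543 read 2652, 24656 and 28232 CPM in the vhx libraries and 26173, 32988 and 5686 in ech_vht_frh.

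Plasmid transcripts differed between strains with no plasmid change named: the 20 genes summed to 280.5 ± 35.1 CPM in ech and 474 ± 34.7 in the parent (n = 3, sums untested). The 645 ± 171 in all_hydrogenase is uncertain, with 1466 unique reads against the parent's 1857. Mbar_A1633, in the file an adenine phosphoribosyltransferase gene, was chosen as hpt candidate for its reads in strains with pac-hpt by label. These reads cannot check that choice: 12, 2 and 5 in ech_frh, 4, 2 and 1 in all_hydrogenase, and 3 in the library labelled ech_vht_frh replicate 3.

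Of the 32 lists tested, 10 were called by camera in none of the 14 comparisons. Their smallest adjusted p-values were 0.0751 for methanol methyltransferases, 0.104 for hydrogenase maturation and 0.209 for iron transport (all in fre against the parent), 0.106 for methyl-coenzyme M reductase (vht_frh against frh), 0.159 for ech genes (vht_frh against the parent), 0.179 for molybdate and tungstate transport (ech_frh against the parent), 0.187 for CRISPR genes (ech_frh against ech), 0.229 for vht and vhx genes (ech_vht_frh against ech_frh), 0.380 for archaellum and chemotaxis (all_hydrogenase against ech_vht_frh) and 0.382 for nickel and cobalt uptake (ech_frh against frh). The pyrrolysine list had too few tested genes.

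Splits of 6 samples into 3 and 3 number 10, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real value and the highest of the other splits were 110 and 0 for fre, 87 and 3 for vhx, 228 and 1 for ech, 181 and 0 for frh, 248 and 0 for ech_frh, 203 and 0 for vht_frh, 1425 and 0 for ech_vht_frh and 1703 and 0 for all_hydrogenase against the parent. They were 22 and 20 for ech_frh and 23 and 0 for vht_frh against frh, 41 and 0 for ech_frh against ech, 996 and 15 for ech_vht_frh against vht_frh, 764 and 222 for ech_vht_frh against ech_frh, and 452 and 226 for all_hydrogenase against ech_vht_frh.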
